A study of Mus musculus with 48 samples.

How the data were processed

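Total RNA from 48 mouse livers was extracted with a Qiagen AllPrep kit, labelled with biotin by the Affymetrix protocol and hybridized to expression arrays, per the labels' protocols. The deposited table held 1 value for each of 41345 probe sets in each array. The values as deposited by the authors ran from -0.51 to 13.42 and were read as log2 expression from that range. The sources used here did not state their unit. The authors' background correction, normalization and software were not given in the sources used here, and no scanner files were used here. The values were used as deposited. An array gives no count of molecules, so the number of arrays sets the precision.

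Gene names came from the platform annotation paired with the probe sets. It listed 25335 probe sets, 23521 with 1 gene symbol and 1814 with several, and left 16010 unlisted. Probe sets with several symbols or none were left out. Of those with 1 symbol, 23328 matched a gene of the RefSeq table of GRCm38.p6, which changed 0 symbols. The genome build behind the probe sets was not given in the sources used here, so no positions are given. A gene was taken as its probe set with the highest mean, which gave 22180 genes, 1082 of them with several probe sets. Genes with a mean above the 30th percentile of all probe set means (1.17) were tested, 16926 in all.

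Each mouse's group was its energy level and its diet composition from the labels, and composition shares were used as numbers. The main model was fitted with limma 3.58.1 (lmFit, eBayes with a trend) in R 4.3.3 to all 48 mice. It held the protein share, the exchange of carbohydrate against fat, and energy level as a factor. The protein slope is the log2 change for 10 points of energy moved to protein from carbohydrate and fat in equal parts, and the exchange slope that for 10 points moved from fat to carbohydrate. High and medium energy were contrasted in this model. Low and high energy at 60/20/20 were contrasted in a model with 1 mean for each of the 20 combinations, and the interaction added the product of both slopes. Tests were two-sided, with Benjamini-Hochberg adjustment over the genes of a comparison and a threshold of 0.05. Fold changes over 55 points are the slope extended from 5% to 60% protein.

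The design, the alternatives, the gene lists and the rule for named genes were set before the data were examined. Named genes were, per comparison, the 12 largest positive and 12 largest negative coefficients among genes past the threshold, or the 5 smallest p where none passed, up to 4 members with the smallest p of each list described, and a fixed set of diet-responsive genes (Fgf21, Asns, Cyp7a1, Scd1, Fasn, Srebf1, Pck1, Cps1, Igf1, Igfbp1, Cpt1a); 1 item is not reported here. Genes named for the medium energy 14/29/57 mouse and for counts of 5 or fewer were chosen after their values were seen. Of 43 gene lists, for metabolic and stress pathways and for markers of other cell types and sex, 41 had 3 or more measured genes and were tested with camera at a preset correlation of 0.01, then with an estimated correlation and with the rotation test fry. List means per mouse were averages of log2 values centred per gene.

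Correlations over mice used 100000 permutations, for which 1e-05 is the smallest p possible. The models were tested on simulated data with 16926 genes and the spread of each gene within diet combinations. Genes varied independently there, unlike on the real arrays. That spread also left out what the single medium energy 14/29/57 mouse adds to the real fits. For protein, 35.8%, 91.0% and 100% of genes with slopes of 0.1, 0.2 and 0.4 were recovered. For high against medium energy, 74.6%, 98.5% and 100% of genes with differences of 0.5, 1 and 2 were recovered, and for low against high at 60/20/20, 41.8%, 95.5% and 100% of differences of 1, 2 and 3. For the interaction 41.8%, 89.6% and 98.5% were recovered at 0.1, 0.2 and 0.4. The share of false calls was 6.79% for protein and between 2.58% and 5.56% for the rest. These shares hold for independent genes only. On the real values, shuffled protein labels tied to the interquartile range of each array gave up to 3857 calls. Recovery may be lower than simulated in the comparisons where that mouse adds spread to the real fit, high against medium energy among them.

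The alternatives changed the filter, the probe set rule, the normalization (quantile, or centring on array medians) or the array weights, or added a term for the Y-linked minus Xist value or for mouse number over 300. Others took the diet combination as a random block, the high energy diets alone, other exchanges for protein, the logarithm of protein, contrasts of matched combinations or the 6 mice alone, or left out each mouse in turn. The interquartile range of each array as a term, that term with the Y-linked minus Xist value, leaving out the 12 arrays of smallest range, and matched contrasts without the pair that held the medium energy 14/29/57 mouse were added after seeing the data. So were the fits without that mouse quoted beside list calls. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.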

Results

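Liver RNA from 48 mice was measured on Affymetrix arrays, 1 array per mouse. The mice had been fed from 3 weeks of age, without restriction, on diets that differed in the share of energy from protein, carbohydrate and fat and in energy density, and their livers were taken at 15 months. Diets are written here as percent of energy from protein, carbohydrate and fat, so that 5/75/20 stands for 5% protein, 75% carbohydrate and 20% fat. The mice filled 20 combinations of composition and energy density with 1 to 4 mice each. Protein supplied 5% of energy in 10 mice, 14% in 9, 23% in 9, 33% in 9, 42% in 5 and 60% in 6. Energy density was high for 29 mice, medium for 14 and low for 5, and all 10 mice on 5% protein ate high energy diets. One mouse was taken from a cage, per the labels, so p-values were taken over separate animals.

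Both sexes entered the study, but the labels did not give the sex of each mouse. In 24 arrays the Y-linked genes lay above Xist (4.07 to 5.86 against 0.74 to 2.01 on the log2 scale), and in the other 24 Xist lay above the Y-linked genes (4.78 to 9.53 against 0.99 to 1.44). Arrays with Y-linked genes above Xist numbered 6 of 10 at 5% protein, 5 of 9 at 14%, 3 of 9 at 23%, 5 of 9 at 33%, 1 of 5 at 42% and 4 of 6 at 60%. The number of arrays limited the precision of each value below. The median of an array lay between 1.57 and 1.86 and its interquartile range between 2.78 and 3.63. Arrays of 1 diet and energy combination correlated at a median r of 0.968 over 43 pairs, against 0.967 over 1085 pairs from different combinations, and no 2 arrays were identical.

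The first question was how liver expression followed the dietary protein share. As protein rose at the expense of carbohydrate and fat in equal parts, 20 of 39 genes of amino acid catabolism and 6 of 8 of the urea cycle rose. Neither list was called with an estimated correlation (camera adjusted p = 0.0978 and 0.0769). Fgf21, Lepr and Cdkn1a were among the genes that fell. With the interquartile range of each array in the model they did not pass the threshold (limma adjusted p = 0.0774, 0.201 and 0.186). Adgrg2 and Slc17a8 fell in both models (limma adjusted p = 1.77e-05 and 0.00119 with that term). Cps1, which commits ammonia to the urea cycle, rose by 0.15 ± 0.02 (SE, n = 48) on the log2 scale for each 10 points of energy from protein, from 11.44 ± 0.42 (SD, n = 10) at 5% protein to 12.30 ± 0.11 (SD, n = 6) at 60% (limma adjusted p = 1.57e-05). Nnmt, which methylates nicotinamide, went from 3.33 ± 1.44 to 7.35 ± 0.18, a fitted change of 19.1-fold over the 55 points between the extreme diets. Fgf21, a liver hormone known to be induced by protein restriction, went the other way, from 8.64 ± 0.58 to 4.62 ± 1.26, with a slope of -0.57 ± 0.12 (adjusted p = 0.00252).

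Of 16926 genes tested, 1187 changed with the protein share, 570 upward and 617 downward, at a Benjamini-Hochberg threshold of 0.05 (limma). With each array centred on its median the split was 309 upward and 683 downward (31.1% upward against 48.0%), and after a further quantile normalization it was 612 upward and 461 downward (57.0%). An unadjusted p under 0.05 was reached by 4510 genes, where chance would give 846. The largest rises per 10 points were those of Lrtm1 (0.84 ± 0.11), Nnmt (0.77 ± 0.11), the estrogen sulfotransferase Sult1e1 (0.68 ± 0.14), the long noncoding RNA Lncbate1 (0.64 ± 0.08), and the acute phase genes Orm2 (0.60 ± 0.13), Orm1 (0.59 ± 0.12) and Orm3 (0.57 ± 0.12). Orm1 stood at 6.58 ± 1.57 at 5% protein and between 9.79 and 10.44 at every higher share. Hamp2 (0.60), Gpx6 (0.55), Ces3b (0.53), Acmsd (0.52), which acts in tryptophan breakdown, and Mup-ps12 (0.51) completed the 12 largest rises. In the model that also held the interquartile range of each array, Orm1 (0.42, adjusted p = 0.0984), Orm2 (0.49, adjusted p = 0.0958), Hamp2 (0.68, adjusted p = 0.0774) and Ces3b (0.35, adjusted p = 0.184) did not pass the threshold. The Orm and Mup families have near-identical members, so their probe sets may share transcripts.

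The largest falls per 10 points were those of the immunoglobulin segment Ighv1-53 (-0.59 ± 0.18), the leptin receptor Lepr (-0.59 ± 0.14), Fgf21, Adgrg2 (-0.57 ± 0.07), Slc17a8 (-0.56 ± 0.08), the proteoglycan Gpc1 (-0.55 ± 0.08) and the cell cycle inhibitor Cdkn1a (-0.51 ± 0.12). Unc13b (-0.48), Csad (-0.48), which makes taurine from cysteine, Tcf24 (-0.48), Ifi27l2b (-0.47) and Slc7a7 (-0.47), a transporter of cationic amino acids, followed. With the interquartile range of each array in the model, Ighv1-53 (-0.40, adjusted p = 0.434), Lepr (-0.38, adjusted p = 0.201), Fgf21 (-0.42, adjusted p = 0.0774), Cdkn1a (-0.37, adjusted p = 0.186) and Tcf24 (-0.30, adjusted p = 0.467) did not pass the threshold. Ighv1-53 also lost its call in 7 and Tcf24 in 11 of the 48 fits that left out 1 mouse. Lepr stood at 8.31 ± 0.62 at 5% protein (n = 10) and at 5.63 ± 1.18 at 14% (n = 9). Fgf21 showed the same step, from 8.64 to 5.67 ± 1.04, and lay between 4.62 and 5.98 at the higher shares. Asns, which makes asparagine, stood at 6.71 ± 0.99 at 5% protein, but its slope of -0.34 ± 0.17 did not pass the test (adjusted p = 0.186). The slopes of Igfbp1 (-0.26 ± 0.10, adjusted p = 0.0821), Igf1 (0.07 ± 0.03, adjusted p = 0.0918), Fasn (-0.18), Cpt1a (-0.09), Cyp7a1 (-0.06), Scd1 (0.06), Pck1 (0.04) and Srebf1 (-0.03) did not pass it either. Cpt1a turned to 0.01 with the interquartile range in the model, and Fasn, Igfbp1 and Srebf1 stood at -0.10, -0.16 and -0.0038. Without the single medium energy 14/29/57 mouse described below Fasn passed (-0.25, adjusted p = 0.0379). Asns passed with the Y-linked minus Xist value in the model (-0.42, adjusted p = 0.0254), but not with the interquartile range (-0.34, adjusted p = 0.534).

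**Figure D1:**
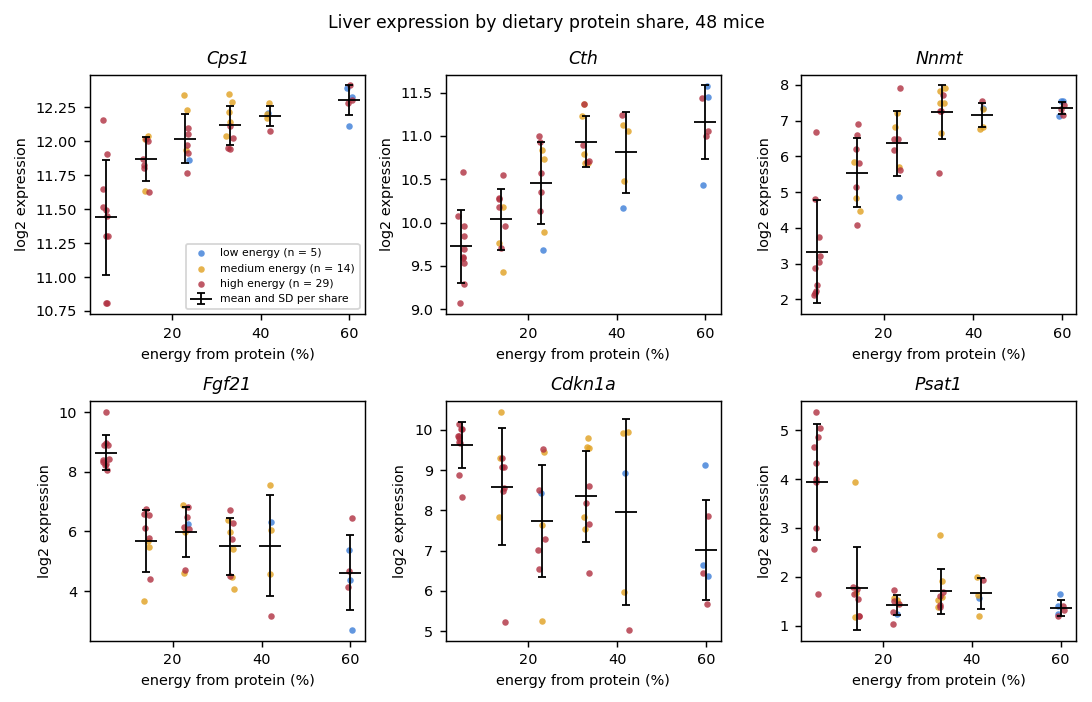
Log2 expression of 6 genes in each mouse against the percent of energy from protein. Points are mice coloured by energy density and shifted slightly sideways, and bars give the mean and SD at each protein share. Mean Cps1 went from 11.44 at 5% protein to 12.30 at 60%, and mean Fgf21 from 8.64 to 4.62.

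Of the 39 measured genes of amino acid catabolism 20 rose and 0 fell over all genes tested, and 23 rose when adjusted over the list alone. Among them were Cth, which cleaves cystathionine (0.33 ± 0.04, 3.47-fold over 55 points, adjusted p = 3.92e-07), Oat (0.34 ± 0.05) and the lysine-degrading Aass (0.28 ± 0.04). All 8 urea cycle genes had positive slopes, and 6 passed the test, 7 when adjusted over the list alone, among them Asl (0.23 ± 0.04), the ornithine carrier Slc25a15 (0.21 ± 0.04) and Otc (0.16 ± 0.04). All 18 genes of branched-chain amino acid catabolism had positive slopes, 13 past the threshold and 16 when adjusted over the list alone, with Acadsb at 0.18 ± 0.03 and Dbt at 0.14 ± 0.02. The set test with a preset correlation of 0.01 (camera) gave adjusted p = 9.4e-21, 6.11e-08 and 2.14e-13 for these 3 lists. The corresponding values were adjusted p = 0.0978, 0.0769 and 0.1 with an estimated correlation, and 0.0184, 0.0188 and 0.0608 when the single medium energy 14/29/57 mouse described below was left out.

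Of 62 measured genes of oxidative phosphorylation 38 rose and 0 fell, 52 when adjusted over the list alone, with Sdhb at 0.18 ± 0.03, Ndufb5 at 0.12 ± 0.02 and Cox5a at 0.11 ± 0.02 (camera adjusted p = 6.1e-30; adjusted p = 0.0978 with an estimated correlation). The tricarboxylic acid cycle list had 3 of 18 genes higher, 7 when adjusted over the list alone, led by Fh1 (0.23 ± 0.04; camera adjusted p = 0.00482; adjusted p = 0.305 with an estimated correlation). The 30 proteasome genes had a median slope of 0.05, and 1, Psmd6, passed the test, 1 also when adjusted over the list alone (camera adjusted p = 1.05e-05; adjusted p = 0.45 with an estimated correlation). The interquartile range of the arrays fell along the same axis, from a mean of 3.48 ± 0.13 (SD, n = 10) at 5% protein to 3.16 ± 0.20 (n = 6) at 60%. With that range in the model, the median slope of oxidative phosphorylation went from 0.10 to 0.05 with 4 genes past the threshold, and that of the proteasome from 0.05 to 0.00 with 0 (camera adjusted p = 1.8e-22 and 0.902). Genes of amino acid catabolism, the urea cycle and branched-chain amino acid catabolism had median slopes of 0.10, 0.13 and 0.07 there (0.12, 0.14 and 0.11 without the term), with 13, 3 and 2 genes past the threshold.

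Of 11 genes of amino acid synthesis 3 fell, 7 when adjusted over the list alone: Psat1 (-0.39 ± 0.09), Aldh18a1 (-0.20 ± 0.06) and Mthfd2 (-0.24 ± 0.07, lost in 15 of the 48 fits that left out 1 mouse) passed over all genes (camera adjusted p = 0.000995; adjusted p = 0.116 with an estimated correlation). Psat1, of the serine pathway, stood at 3.94 ± 1.19 at 5% protein and between 1.37 and 1.77 above it. Among 30 targets of the stress factor ATF4, 8 fell and 1, Cth, rose, and 14 fell when adjusted over the list alone. Fgf21, Slc7a5 (-0.21 ± 0.05) and Nupr1 (-0.29 ± 0.07) led the falls (camera adjusted p = 7.2e-05; adjusted p = 0.305 with an estimated correlation). In the list of 10 p53 and ageing genes Cdkn1a and Trp53inp1 (-0.18 ± 0.05) fell, 2 genes also when adjusted over the list alone (camera adjusted p = 0.0326; adjusted p = 0.305 with an estimated correlation). With the interquartile range in the model none of these falls passed the threshold for a single gene, and Psat1 and Fgf21 had slopes of -0.34 (adjusted p = 0.116) and -0.42 (adjusted p = 0.0774).

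Of 17 genes for lipid droplets and storage, Cidec, which enlarges lipid droplets (-0.41 ± 0.10), and Pparg (-0.29 ± 0.06) fell, 5 genes when adjusted over the list alone (camera adjusted p = 0.0167; adjusted p = 0.305 with an estimated correlation). Among 36 genes of fatty acid oxidation and PPAR alpha targets 5 fell, among them Fgf21, Acot2 (-0.34 ± 0.10) and Cyp4a31 (-0.30 ± 0.09), and 6 fell and 1 rose when adjusted over the list alone (camera adjusted p = 0.0326; adjusted p = 0.718 with an estimated correlation). With the interquartile range in the model 0 genes of either list fell past the threshold (Cidec adjusted p = 0.125, Pparg 0.126), the median slope of the storage list went from -0.08 to -0.03, and the oxidation list was not called (camera adjusted p = 0.110). The list call for unfolded protein response genes was also downward with a median slope of -0.04 and 1 of 23 genes past the threshold, Derl3, 0 when adjusted over the list alone (camera adjusted p = 0.0202; adjusted p = 0.693 with an estimated correlation). Derl3 lost its call in 23 of the 48 fits that left out 1 mouse and with the interquartile range (adjusted p = 0.187).

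Several marker lists of cells other than hepatocytes were called downward, while that of skeletal muscle was called upward. All 17 stellate cell and fibrosis genes had negative slopes, 5 passed, 10 when adjusted over the list alone, and Col1a1 stood at -0.32 ± 0.09 and Tgfb1 at -0.20 ± 0.05 (camera adjusted p = 1.48e-05; adjusted p = 0.305 with an estimated correlation). The lymphocyte, endothelial and macrophage lists were called downward with median slopes of -0.11, -0.09 and -0.11 and no single gene past the threshold, also when adjusted over the list alone (camera adjusted p = 0.00195, 0.00257 and 0.0326; adjusted p = 0.45, 0.45 and 0.725 with an estimated correlation). With the interquartile range in the model, these 4 median slopes were -0.05, -0.06, -0.01 and -0.04 and 0 genes of the 4 lists passed (Col1a1 -0.17, adjusted p = 0.486; Tgfb1 -0.09, adjusted p = 0.492). The endothelial and macrophage calls were lost there (camera adjusted p = 0.335 and 0.205). The interferon list was called downward, with 3 of 15 genes lower, and 3 when adjusted over the list alone (camera adjusted p = 0.0437, and 0.598 with an estimated correlation). These genes, Iigp1, Oasl2 and Ifit2, lost their calls in 10, 14 and 33 of the 48 fits that left out 1 mouse. With the interquartile range in the model Iigp1 passed (limma adjusted p = 0.0383), but Oasl2 and Ifit2 did not (0.728 and 0.594). Without the single medium energy 14/29/57 mouse described below, the macrophage and interferon calls were lost (camera adjusted p = 0.235 and 0.0978).

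The list of liver genes higher in males was called upward with 2 of 20 genes past the threshold, Cyp2f2 (0.26 ± 0.07) and Nudt7 (0.32 ± 0.09), 3 when adjusted over the list alone (camera adjusted p = 0.000394; adjusted p = 0.598 with an estimated correlation). That call was lost with the interquartile range in the model (adjusted p = 0.183), as were those of Cyp2f2 (adjusted p = 0.199) and Nudt7 (adjusted p = 0.360). The bile acid, xenobiotic and skeletal muscle lists were called upward near the threshold (camera adjusted p = 0.0437, 0.0437 and 0.0497; adjusted p = 0.68, 0.598 and 0.441 with an estimated correlation). They held 2 of 16, 1 of 19 and 0 of 10 genes that rose, and 2, 2 and 0 when adjusted over each list alone. In the xenobiotic list 2 genes fell, Alas1 (-0.17 ± 0.05) and Cyp3a11 (-0.14 ± 0.05), neither past the threshold with the interquartile range in the model (adjusted p = 0.338 and 0.213), and Cyp3a11 lost its call in 27 of the 48 fits that left out 1 mouse. These 3 calls were lost without the same medium energy mouse (adjusted p = 0.419, 0.173 and 0.0514) and with the interquartile range in the model (adjusted p = 0.109, 0.182 and 0.950). By the rotation test fry 10 of 41 lists were called, 6 with the interquartile range in the model and 15 without that mouse. With camera 21 of 41 lists were called at the preset correlation, 0 of them with an estimated correlation, and 21 and 2 (amino acid catabolism and the urea cycle) without that mouse. The 5 calls gained without it were downward for fatty acid synthesis (camera adjusted p = 0.000317; adjusted p = 0.448 with an estimated correlation), liver genes higher in females (0.0255; adjusted p = 0.671 with an estimated correlation), cholesterol synthesis (0.00563) and mTOR signalling (0.0190; adjusted p = 0.528 for both with an estimated correlation), and upward for autophagy (0.0479; adjusted p = 0.368 with an estimated correlation).

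**Figure D2:**
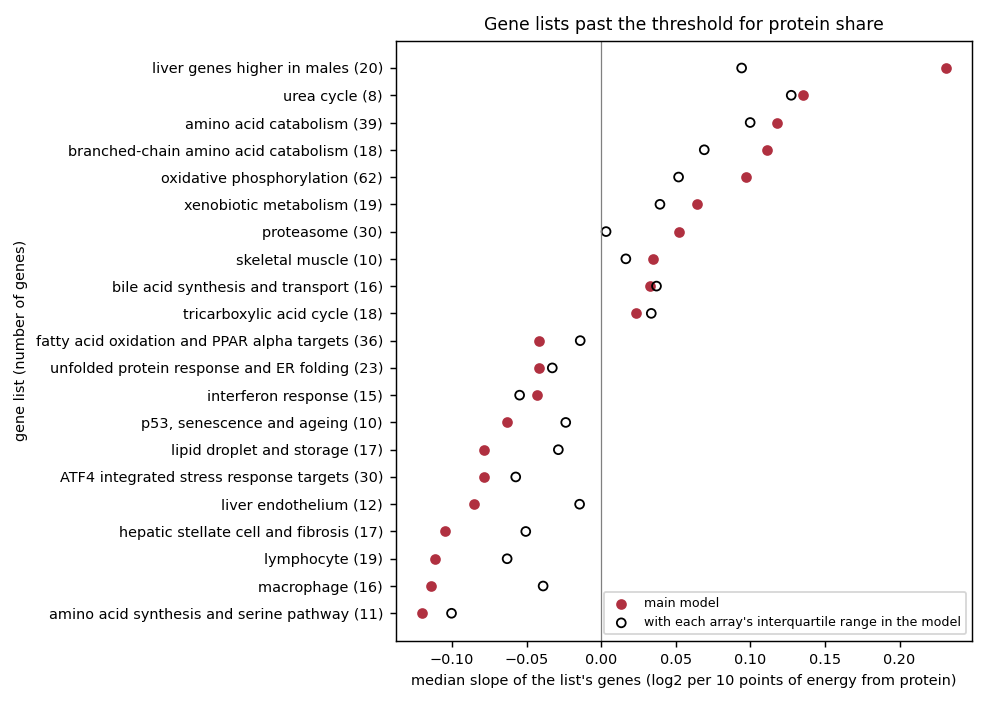
Median slope of each gene list called for protein share, in log2 units per 10 points of energy from protein, with the number of measured genes in brackets. Filled points are from the main model and open points from a model that also holds the interquartile range of each array. The urea cycle median was 0.14 without and 0.13 with that term, and the proteasome median 0.05 and 0.00.

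The protein share correlated with the interquartile range of the array at Pearson r = -0.43 (permutation p = 0.00215, adjusted p = 0.00645) and Spearman rho = -0.52 (permutation p = 0.00021, adjusted p = 0.00056) over 48 mice, 1 of 6 relations computed, and at r = -0.47 without the 2 mice farthest from the median share. Within the mice numbered under 300 in the labels r was -0.48 (n = 34, rho = -0.60), and within those over 300 it was -0.48 (n = 14, permutation p = 0.0827, rho = -0.48), but -0.17 without 2 mice. Within the high energy diets r was -0.42 (n = 29, rho = -0.61). With the range in the model 113 genes were called, 100 of them among the 1187, and all 1187 kept the sign of the slope. The 100 held 64 genes that rose and 36 that fell, among them Cps1, Cth, Oat, Nnmt, Lrtm1, Acmsd, Adgrg2 and Csad. Leaving out the 12 arrays with the smallest range gave 334 calls.

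**Figure D3:**
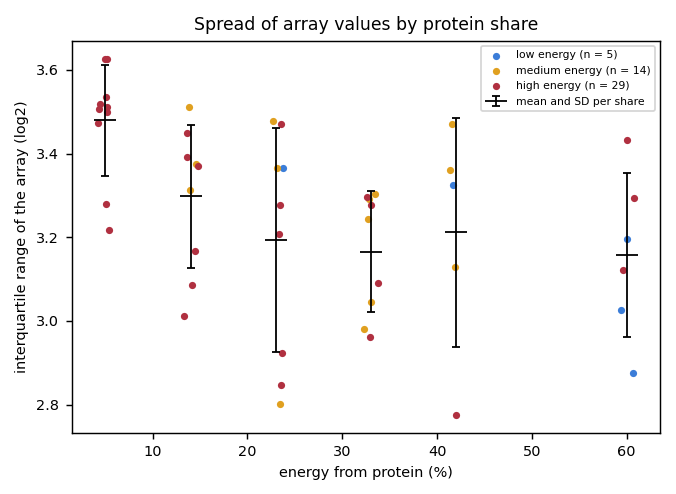
Interquartile range of the log2 values of each array against the percent of energy from protein. Points are mice coloured by energy density and shifted slightly sideways, and bars give the mean and SD at each share. The mean was 3.48 at 5% protein and 3.16 at 60%.

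Leaving out single mice moved the protein count by over 1.5 times in 9 cases. It was 2147, 3004 and 620 without high energy 60/20/20 replicates 1, 2 and 3, 588 without high energy 42/29/29 replicate 1, 726 and 743 without high energy 5/20/75 replicates 1 and 2, and 784, 778 and 758 without high energy 5/48/48 replicates 1, 3 and 4. The interquartile ranges were 3.29, 3.43 and 3.12 in those 60/20/20 arrays, 2.78 in the 42/29/29 array and 3.51 to 3.63 in those on 5% protein. The arrays whose loss raised the count thus ran against the fall of the range with protein, and the others ran with it. Whether the range accounts for these shifts was not tested.

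The next question was what changed when energy moved from fat to carbohydrate at a fixed protein share. Lipogenic genes had the largest positive slopes among the always-named genes in the full set, but no gene passed the threshold. Without the medium energy 14/29/57 mouse Cyp7a1 (0.18) lay above Fasn (0.15). Scd1, the stearoyl-CoA desaturase, had a slope of 0.27 ± 0.07 (SE, n = 48) per 10 points moved from fat to carbohydrate (limma adjusted p = 0.991), and Fasn one of 0.23 ± 0.11 (adjusted p = 0.999), which was 0.15 without the medium energy 14/29/57 mouse. Elovl6 stood at 0.33 ± 0.10, Acaca at 0.20 ± 0.06 and Me1 at 0.27 ± 0.10. The list of 20 fatty acid synthesis genes was called upward, with 18 positive slopes, 0 genes past the threshold and 4 when adjusted over the list alone (camera adjusted p = 7.12e-09; adjusted p = 0.388 with an estimated correlation).

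The limma count was 0 of 16926 genes, where 665 reached an unadjusted p under 0.05 and chance would give 846. The count was 2 with array weights (Cables1 and Ccl2), 1 in the high energy diets alone (Ccl2), 1568 in a contrast of matched diet combinations and 0 in that contrast without the pair that held the medium energy 14/29/57 mouse. The 5 smallest p belonged to Cables1 (-0.17 ± 0.04), the chemokine Ccl2 (-0.23 ± 0.05), Olfr1395 (-0.10 ± 0.02), Tent5c (-0.17 ± 0.04) and Ccdc59 (0.09 ± 0.02), with adjusted p from 0.449 upward. The other always-named genes had slopes of 0.20 ± 0.09 (Cyp7a1), 0.08 ± 0.02 (Cps1), -0.09 ± 0.11 (Igfbp1) and between -0.02 and 0.03 for Fgf21, Asns, Srebf1, Pck1, Igf1 and Cpt1a (-0.05 to 0.02 without that mouse). On the simulated values 89.6% of genes with a slope of 0.2 were recovered in this comparison, and 37.3% of those with a slope of 0.1. Those values leave out the spread that the medium energy 14/29/57 mouse adds to the real fit, so the real shares may be lower.

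Immune markers were called downward as carbohydrate replaced fat. The 19 lymphocyte genes had 18 negative slopes, 0 past the threshold and 6 lower when adjusted over the list alone, with Nkg7 at -0.20 ± 0.06, H2-Aa at -0.24 ± 0.08 and Ccl5 at -0.25 ± 0.09 (camera adjusted p = 9.05e-13; adjusted p = 0.142 with an estimated correlation). The macrophage and interferon lists were called downward too, with 0 genes past the threshold, also when adjusted over each list alone (camera adjusted p = 9.97e-09 and 6.45e-06; adjusted p = 0.388 and 0.319 with an estimated correlation). Without the medium energy 14/29/57 mouse the median slopes of these 3 lists went from -0.13, -0.15 and -0.08 to -0.11, -0.08 and -0.07. All 3 calls held at the preset correlation (camera adjusted p = 5.49e-12, 2.98e-05 and 7.24e-05), but 0 lists were called with an estimated correlation or by fry. The mouse with the next highest macrophage and lymphocyte means (1.41 and 1.14), high energy 14/29/57 replicate 4, had the same composition and stayed in that fit. The cell cycle, stellate cell, endothelial, blood and p53 lists were also called downward (camera adjusted p = 0.00282, 0.00327, 0.00327, 0.0197 and 0.0314; adjusted p = 0.388 to 0.49 with an estimated correlation). The blood and p53 calls were lost without that mouse (adjusted p = 0.518 and 0.0512). The upward calls for amino acid catabolism (38 of 39 slopes positive), cholesterol synthesis (20 of 20), glycolysis and fructose handling (9 of 12), the urea cycle (8 of 8) and liver genes higher in males (19 of 20), with positive slopes counted in the full set, also passed without it (camera adjusted p = 0.00539, 0.0465, 0.00539, 0.036 and 0.00539; adjusted p = 0.305 to 0.59 in the full set with an estimated correlation). Their median slopes went from 0.03, 0.06, 0.07, 0.06 and 0.15 to 0.02, 0.02, 0.04, 0.04 and 0.12 without that mouse. Over these 5 lists 0 genes passed the threshold, and 1 urea cycle gene did when adjusted over the list alone. The upward calls for bile acid synthesis, xenobiotic metabolism, NRF2 targets and the tricarboxylic acid cycle were lost without it (adjusted p = 0.257, 0.324, 0.261 and 0.498; adjusted p = 0.49 to 0.493 in the full set with an estimated correlation). Gained without it were downward calls for the acute phase (0.0286) and fatty acid oxidation (0.0397) and an upward call for the cytosolic ribosome (0.0465; adjusted p = 0.764 for each with an estimated correlation). In all 18 of 41 lists were called, 0 with an estimated correlation and 0 by the rotation test fry.

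**Figure D4:**
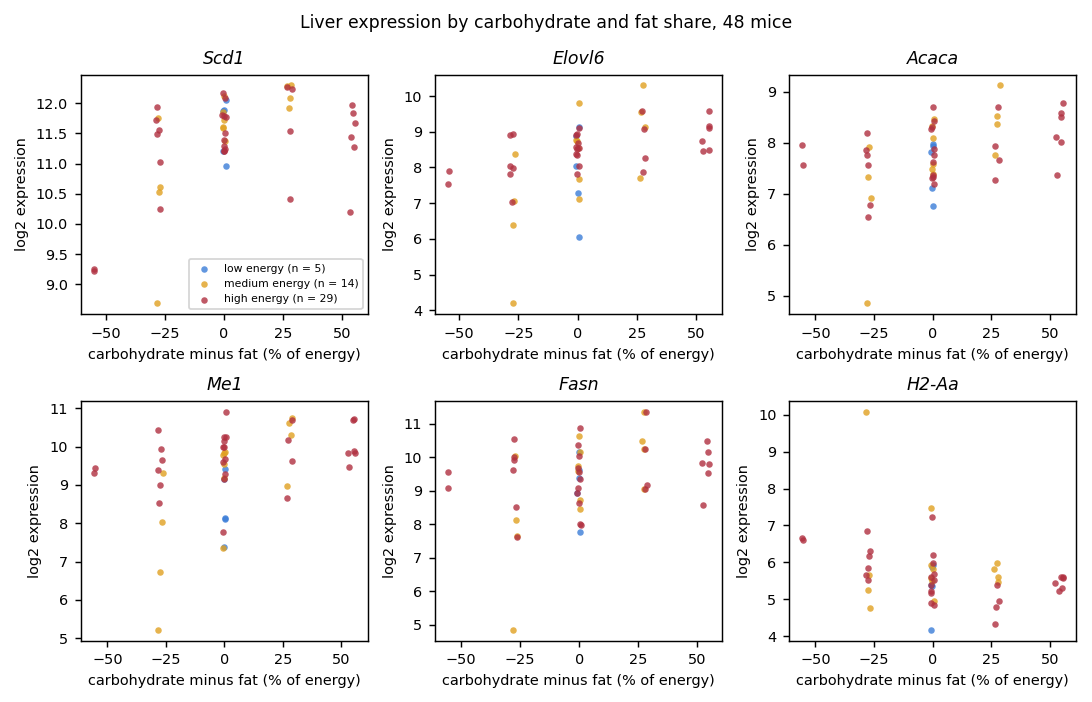
Log2 expression of 5 lipogenic genes and the antigen-presenting gene H2-Aa in each mouse against the carbohydrate share minus the fat share, in percent of energy. Points are mice coloured by energy density and shifted slightly sideways. No gene passed the threshold for this slope, and Scd1 had a slope of 0.27 ± 0.07 per 10 points moved from fat to carbohydrate.

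High and medium energy density were compared with composition held in the model as straight-line slopes. All 10 mice on 5% protein ate high energy diets. A step at 5% protein that a line misses can therefore enter this difference. The list of fatty acid oxidation and PPAR alpha targets was called higher on high energy diets at the preset correlation. All 36 members had positive differences with a median of 0.24 on the log2 scale, and 0 passed over all genes and 15 when adjusted over the list alone (camera adjusted p = 8.14e-16; adjusted p = 0.324 with an estimated correlation; fry adjusted p = 0.0984). Decr1 differed by 0.38 ± 0.09 (SE, 29 against 14 mice), Acaa1a by 0.36 ± 0.10, Eci1 by 0.38 ± 0.11 and Eci2 by 0.27 ± 0.08. Without the medium energy 14/29/57 mouse the median of this list was 0.17 (camera adjusted p = 3.56e-12).

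The limma count for single genes was 0, with 1376 at an unadjusted p under 0.05. It was 2 with the Y-linked minus Xist value in the model (Btg2 and Mmd), 1899 in a contrast of the matched combinations, and 2 in that contrast without the pair that held the medium energy 14/29/57 mouse (Eml4 and Ube2t). The smallest p were those of the growth inhibitor Btg2 (-1.16 ± 0.22, adjusted p = 0.0609), Fst (-0.72 ± 0.16), Abhd6 (0.50 ± 0.11), Sgo2a (-0.49 ± 0.11) and Tmprss2 (-0.87 ± 0.20), the last 4 at adjusted p = 0.192. Fgf21 differed by 0.76 ± 0.41, Igfbp1 by -0.64 ± 0.34, Asns by 0.64 ± 0.59, Cyp7a1 by 0.48 ± 0.30 and Cps1 by -0.23 ± 0.08, none past the threshold. Scd1, Fasn, Srebf1, Pck1, Igf1 and Cpt1a differed by -0.15, 0.08, 0.12, 0.08, 0.03 and 0.22, also short of it, and by -0.35, -0.30, -0.02, -0.01, -0.03 and 0.11 without that mouse.

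The cell cycle list was called lower on high energy diets, with Mki67 at -0.78 ± 0.24 and Cdk1 at -0.53 ± 0.18, 0 of 20 genes past the threshold and 1 when adjusted over the list alone (camera adjusted p = 9.21e-08; adjusted p = 0.342 with an estimated correlation). The macrophage list had a median difference of -0.48, and -0.20 without the medium energy 14/29/57 mouse, with 0 of 16 genes past the threshold, also when adjusted over the list alone (camera adjusted p = 9.21e-08 and 0.0015; adjusted p = 0.342 with an estimated correlation). Cd14 stood at -0.81 ± 0.29 with that mouse and -0.39 without it. The lymphocyte, blood, stellate cell, acute phase, bile duct and p53 lists were also called lower, and passed without it (camera adjusted p = 0.00695, 0.0126, 0.000754, 3.84e-07, 0.000691 and 0.0302). In the full set they had adjusted p = 0.342 to 0.543 with an estimated correlation. The lymphocyte median went from -0.26 to -0.13 and the blood median from -0.56 to -0.15 without that mouse. Branched-chain amino acid catabolism, proteasome and liver genes higher in males were called higher and passed without it (camera adjusted p = 0.0125, 0.0079 and 0.000456; adjusted p = 0.342, 0.617 and 0.543 with an estimated correlation in the full set). Their medians went from 0.17, 0.08 and 0.67 to 0.06, 0.05 and 0.50. The calls for bile acid synthesis, cholesterol synthesis, the tricarboxylic acid cycle, xenobiotic metabolism and oxidative phosphorylation (higher) and the cytosolic ribosome (lower) were lost without it (adjusted p = 0.0699, 0.74, 0.269, 0.382, 0.336 and 0.924; adjusted p = 0.342 to 0.737 in the full set with an estimated correlation). Urea cycle genes, amino acid catabolism genes and liver genes higher in females, not called in the full set, were called lower without it (adjusted p = 0.00554, 0.000456 and 0.0178; adjusted p = 0.432, 0.480 and 0.701 with an estimated correlation; fry adjusted p = 0.555, 0.668 and 0.792). In all 18 of 41 lists were called, 0 with an estimated correlation and 0 by fry.

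Low and high energy density were compared at 60/20/20, with 3 mice each. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, had the largest difference of the always-named genes, -1.87 ± 0.59 (low minus high), which did not pass the threshold (limma adjusted p = 0.376). The 5 smallest p belonged to Dnaic2 (0.58 ± 0.12), the palmitoyltransferase Zdhhc13 (-1.23 ± 0.26), Elac1 (-1.61 ± 0.34), the protease inhibitor Spink5 (-1.08 ± 0.23) and Mir3961 (1.40 ± 0.31), each at adjusted p = 0.153. Igfbp1 differed by 1.09 ± 0.74, Fgf21 by -0.93 ± 0.73, Cpt1a by -0.66 ± 0.34, Igf1 by -0.38 ± 0.19, Scd1 by -0.36 ± 0.36 and Asns by -0.29 ± 1.14. Fasn, Srebf1, Cps1 and Pck1 differed by -0.21, -0.17, -0.06 and -0.01. A term for the interquartile range turned Fasn, Srebf1 and Pck1 to 0.37, 0.13 and 0.06, with Fgf21, Cpt1a, Asns and Cps1 at -0.57, -0.21, -1.03 and -0.04. The limma count was 0, with 1710 genes at an unadjusted p under 0.05, 12 genes with array weights and 0 from the 6 mice alone. Without the 12 arrays of smallest interquartile range the count was 39, but 2 of the 12 were low energy 60/20/20 mice, so 1 mouse made up that side, the spread came from other combinations, and the count says nothing about replicates.

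The last comparison asked whether the carbohydrate and fat slope changed with the protein share. Fgf21 (-0.16 ± 0.12), Srebf1 (0.09 ± 0.05) and Cps1 (-0.05 ± 0.02) had interaction terms, per 10 points of each, that did not pass the threshold (limma adjusted p = 0.967 for each). The smallest p were those of Ift140 (0.13 ± 0.03), D030056L22Rik (-0.14 ± 0.04), Gm9234 (-0.13 ± 0.03), Fmn1 (0.13 ± 0.03) and H60b (-0.08 ± 0.02), also at adjusted p = 0.967. The other always-named genes had terms between -0.13 and 0.09. The limma count was 0, with 652 genes at an unadjusted p under 0.05, and 1 with array weights (Ift140).

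The medium energy 14/29/57 mouse, the single mouse of its combination, stood apart from all others. In it 982 of 22180 genes lay more than 1 log2 unit above every other mouse and 379 more than 1 unit below, against 39 genes in total for the next array. Chil3 stood at 11.20 against a mean of 1.24 ± 0.53 (SD, n = 47), F13a1 at 10.92 against 1.60, Itgam at 10.49 against 3.07 and Trem2 at 9.53 against 3.18, all genes known from myeloid cells. The mean of the macrophage list, centred per gene, was 3.87 in this mouse and at most 1.41 in the other 47. The lymphocyte mean was 2.20 against at most 1.14, and the blood mean 4.33 against at most 1.15. Some lists of hepatocyte functions lay below every other mouse, with bile acid synthesis at -2.34 against at least -0.35 and amino acid catabolism at -1.54 against at least -0.52. Oxidative phosphorylation (-0.35), acute phase (0.14) and lipid droplet (0.19) means lay inside the range of the others.

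**Figure D5:**
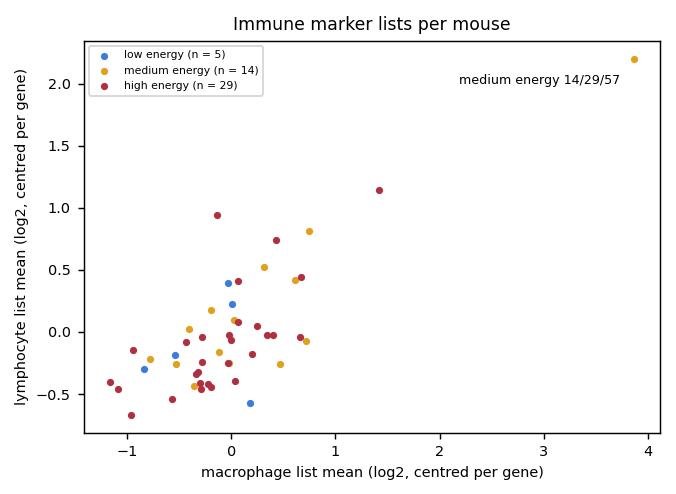
Mean of the macrophage list against the mean of the lymphocyte list in each mouse, in log2 units centred per gene over all mice. Points are mice coloured by energy density. The medium energy 14/29/57 mouse lies at 3.87 and 2.20, apart from the other 47.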

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

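Chosen after the results were seen were the fits with the interquartile range, the use of the planned fit with the Y-linked minus Xist value as a test of unequal sexes, and the macrophage and array quality tests of the single medium energy 14/29/57 mouse.

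The first pattern was the 1187 protein calls beside the falling interquartile range of the arrays. Chance was argued against but not excluded. Of 100 splits 1, the real one, gave as many calls, the smallest share 100 splits can give, and the highest other gave 5. Among 100 splits tied as strongly to the interquartile range 21 gave as many, the highest other 3857. A chance tie of protein to the range can thus give as many calls, and for the calls as a whole array or RNA quality stays open. For the 100 calls that held with the range in the model, chance together with the range was argued against. Of those 100 splits 1, the real one, gave as many calls there (113, the highest other 1). Shuffled protein labels carry nothing beyond the range, so these splits cannot weigh array or RNA quality that the range leaves out. The 1087 lost calls cannot be told apart from it, because their slopes shrank to a median of 0.590 of their size, from 0.13 to 0.08, while the median SE went from 0.04 to 0.03. Loss of long transcripts stays open over all genes, since gene length and protein slope had a Spearman rho of -0.263 over 16811 genes, which are not independent replicates, and 0.0496 with the range in the model. Unequal sexes were argued against as the whole cause, since 1032 genes were still called with the Y-linked minus Xist value in the model. That value is not sex alone, since Xist correlated with the range at r = 0.86 over the 24 arrays with Xist above the Y-linked genes. The 5% protein diets alone stay open as a cause. Without those 10 mice 100% of called genes kept their sign, but the genes were chosen by slopes that included the other 38 mice. Then 14 calls passed and the slopes shrank to a median of 0.726 of their size. A response of the liver to protein may account for the 100 kept calls, though quality that the range leaves out stays open.

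The second pattern was the profile of the medium energy 14/29/57 mouse. Poor array quality of the kind that goes with a small interquartile range was argued against, since 43 arrays had a smaller range than its 3.51. The range comes from the same values as the profile, so other faults of the array stay open. Myeloid cells stay open for the raised genes, since its macrophage list mean lay 2.46 above the highest of the other 47. Whether they account for the genes below every other mouse was not tested. Those falls were uneven, with list means of -2.34 for bile acid synthesis, -1.06 for the urea cycle and -0.50 for lipoproteins. Red cells were argued against as the whole cause. The red cell genes Slc4a1 and Epb42 averaged 4.26, only 0.464 above the highest other mouse. Yet no other array had more than 39 genes lying over 1 log2 unit outside all others, against 1361 here. Red cells stay open for a part of the raised genes. Other blood cells also stay open, since the blood list mean was 4.33 against at most 1.15 in the other 47. Whether such cells came from disease of the animal, from its diet or from the piece of tissue taken was not tested, as no other mouse shared its combination.

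The third pattern was the set of list calls. For protein, 2 of 100 splits called as many as the real 21 lists, the real one included, with 25 in the highest other. Chance was argued against at that share but not excluded, since another split called more. Splits tied to the interquartile range were not run for lists, so array or RNA quality stays open for these calls. For the carbohydrate and fat exchange chance stays open, since 11 of 100 splits called 18 or more (highest other 21). For high against medium energy chance stays open too, since 15 of 100 splits called 18 or more (highest other 21). The median split called 11 or 12 lists, in line with correlated genes that the preset correlation leaves out.

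Where the real count was 0 every split gives at least as many by construction, so the 100 of 100 splits for the exchange (highest other 3), for high against medium energy (highest other 1) and for the interaction (highest other 1) say nothing about chance. The same holds for low against high energy (real count 0, highest other 1), where the 10 splits are also too few for a share under 0.05.

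In 8 of 126 sets of values from 4 mice of 1 group, 1 mouse lay far from the others; chance gives about 5% of sets. In high energy 5/48/48, Cpt1a was 10.22 in replicate 2 (others 10.84 to 10.92), the urea cycle mean was -0.61 in replicate 1 (others -0.32 to -0.28) and the p53 and ageing mean was 0.55 in replicate 4 (others 0.36 to 0.37). In the same group the bile acid mean was 0.20 in replicate 2 (others -0.26 to -0.20) and the xenobiotic mean 0.23 in replicate 3 (others -0.26 to -0.24). The lymphocyte mean was 1.14 in high energy 14/29/57 replicate 4 (others -0.14 to 0.05). In high energy 5/75/20 the bile duct mean was 0.33 in replicate 2 (others -0.30 to -0.25) and the interquartile range 3.22 in replicate 1 (others 3.47 to 3.52).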

How the results depend on the processing

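The settings with the interquartile range, without the 12 arrays of smallest range and matched without 1 mouse were chosen after seeing the data. No paired analysis was possible because mouse numbers in the labels are unique to each animal and replicate numbers only follow accession order. The log2(value + 1) alternative was not run, since the values are already on a log2 scale. The protein count of 1187 stayed within 1.5 times with other filters, probe set rules, normalizations, the sex term, the mouse number block and high energy diets alone (797 to 1597). It was 4301 with array weights, 3652 on the logarithm of protein, 630 with the diet combination as a random block, 263 when protein replaced carbohydrate and 719 when it replaced fat, 113 with the interquartile range, 133 with that and the Y-linked minus Xist value, and 334 without the 12 arrays; leaving out 1 mouse gave 588 to 3004. Of 1773 values of named protein genes under other settings 194 lost and 64 gained a call and 0 reversed. A value counted as reversed only if its sign changed and either fit held a call, so the turn of Cpt1a, never called there, did not count.

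The exchange count of 0 became 2 with array weights, 1 in the high energy diets and 1568 with matched combinations, which was 0 without the medium energy 14/29/57 mouse and the pair it belonged to (4 pairs in place of 5), so mouse and pair cannot be separated; leaving out 1 mouse gave 0 each time. High against medium energy gave 2 with the Y-linked minus Xist value, 4 with that and the interquartile range (Btg2, Decr1, Mgll, Mmd), 1 without the 12 arrays (G0s2), 1899 with matched combinations and 2 without that mouse and its pair (5 pairs in place of 6), and 0 to 3 leaving out 1 mouse (Btg2, Fst and Pdilt without medium energy 23/38/38 replicate 1). Low against high energy gave 12 with array weights, 39 without the 12 arrays, with 1 low energy mouse left, and 0 to 5 leaving out 1 mouse (Tcta, Ncaph, Obox3, Ndrg3 and 4932438H23Rik without low energy 60/20/20 replicate 3). The interaction gave 1 with array weights and 0 leaving out any 1 mouse. With an estimated correlation 0 lists were called for protein, exchange and energy (smallest adjusted p 0.0769, 0.142 and 0.324), against 2 for protein without the medium energy 14/29/57 mouse (amino acid catabolism and urea cycle), and fry called 10, 0 and 0; leaving out 1 mouse gave 16 to 24, 14 to 20 and 15 to 20. For the other changes the cause was not tested. Dim probe sets lie close to the array background, which limits what they can show.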

Other observations

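The tests of sex here, the fits with the interquartile range and those without 1 mouse were chosen after the results were seen.

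Some gene groups that did not pass as lists held single genes that changed with protein. Of 13 lipoprotein genes Apoc1 (0.09), Apoc3 (0.07) and Apoc2 (0.08) rose and Apoa4 fell (-0.25 per 10 points), and the list was not called (camera adjusted p = 0.504). Of 17 autophagy and lysosome genes Atg5 (0.15), Gabarapl1 (0.10) and Lamp2 (0.05) rose (camera adjusted p = 0.101). Of 22 mTOR and insulin signalling genes Mtor fell (-0.22) and the insulin receptor adaptor Grb14 rose (0.08; camera adjusted p = 0.0501). Of 20 cholesterol genes Ebp and Fdx1 rose (0.13 each) and Srebf2 (-0.18) and Mvd (-0.22) fell (camera adjusted p = 0.177). With the interquartile range in the model 0 genes of these 4 lists rose past the threshold, Apoa4 still fell (adjusted p = 0.0464), the cholesterol and cytosolic ribosome lists were called downward (camera adjusted p = 0.000162 and 1.75e-08; fry adjusted p = 0.440 and 0.211; median slopes -0.09 and -0.05) and the mTOR median turned from -0.08 to 0.02. Without the medium energy 14/29/57 mouse the cholesterol, mTOR, fatty acid synthesis and female-biased lists were called downward (camera adjusted p = 0.00563, 0.0190, 0.000317 and 0.0255) and the autophagy list upward (0.0479). They had adjusted p = 0.528, 0.528, 0.448, 0.671 and 0.368 with an estimated correlation.

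Arrays with Xist above the Y-linked genes differed in the level of Xist itself, from 4.78 to 9.53. Over these 24 arrays Xist correlated with the interquartile range at Pearson r = 0.86 and Spearman rho = 0.90 (permutation p = 1e-05 for each, adjusted p = 6e-05, the smallest the permutations can give before adjustment), and at r = 0.82 without the 2 mice farthest from the median. Xist is a long RNA, and gene length correlated with the coefficient of the interquartile range at a Spearman rho of 0.362 across genes, which are not independent replicates. Loss of long transcripts on arrays of small range may account for both, as the length test of protein slopes (rho = -0.263, and 0.0496 with the range in the model) also leaves open.

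A hypothesis that protein slopes differ between male and female livers was tested as the interaction of protein with the Y-linked minus Xist value. In limma 0 genes passed and 404 reached an unadjusted p under 0.05, where chance would give 846, so these data give it no support. The test is limited because that value mixes sex with the interquartile range in the arrays with Xist above the Y-linked genes. A difference of the protein slope between high and medium energy diets, tested in 43 mice, was passed by 0 genes in limma, with 958 at an unadjusted p under 0.05 and a smallest adjusted p of 0.516.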
